A study of Rattus norvegicus with 24 samples.

How the data were processed

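The series holds 24 samples of primary rat hepatocytes kept in sandwich culture, in which the cells lie between layers of matrix so that they keep liver functions for longer. The cells were exposed for 24 h to 1 of 4 piperazine designer drugs, each at its EC20, the concentration with an effect of 20 percent, per the labels. The concentrations were 625 µM for BZP, 35 µM for TFMPP, 522 µM for MeOPP and 467 µM for MDBP. Each drug has 3 treated samples, and the labels name for every treated sample its own control with 0.1 percent DMSO, which gives 8 groups of 3 and 12 pairs. Per the labels' protocols, RNA was extracted with QIAzol and 100 ng was labelled for an Affymetrix rat expression array.

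The deposited table holds log2 expression values made by RMA, per the submitters' processing notes. RMA corrects the background, applies quantile normalization and summarises the probes of each probe set. The RMA version is not given in the sources used here. Array medians lay between 4.448 and 4.519 and values between 1.431 and 14.1, so the values were used as deposited, with no further normalization. Arrays carry no read depth, and the number of arrays limits the precision. Of 31099 probe sets, 57 Affymetrix controls were left out and 31042 were tested. The platform table gave 1 gene symbol for 20826 probe sets, several for 436 and none for 9780. No symbol needed an update through its gene identifier, and 68 were kept as the platform table gives them. A gene was represented by its probe set with the highest mean over all arrays, which gave 14217 genes. Probe sets of the same gene were called in opposite directions for the mean of the drugs in 49 of 4525 genes with several.

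All 24 arrays entered a single linear model in limma 3.58.1 under R 4.3.3, with 12 pair terms and 4 drug terms. This left 8 residual degrees of freedom, with 7.66 added by the empirical Bayes prior. Moderated two-sided tests were made for each drug, for the mean of the 4 drugs and for the 6 differences between drugs. The p-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, and an adjusted p under 0.05 was called a change. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15. Changes are given on the log2 scale as treated minus paired control, with the standard error (SE) of the model. The labels do not say whether samples came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

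The pairing was taken from the titles of the controls and checked in the data. The deviations of each treated array and its named control from their group means correlated at 0.612 to 0.802 in all 12 pairs. Clustering of the 12 DMSO arrays, made after the arrays were seen, placed them in 5 sets, called preparations below. DMSO arrays correlated at 0.9943 to 0.9971 within a preparation and at 0.9622 to 0.9919 between preparations. Preparation 1 held the first pair of every drug, preparation 2 the second pairs of BZP, TFMPP and MeOPP, preparation 3 the third pairs of BZP and MDBP, preparation 4 the third pairs of TFMPP and MeOPP, and preparation 5 the second pair of MDBP. The labels name no such batch. List medians are therefore given by preparation beside the pooled value.

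The 24 gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The lists covered cholesterol synthesis, sterol regulation and uptake, fatty acid and triglyceride synthesis, fatty acid oxidation with PPAR alpha targets, AHR targets, CAR and PXR targets, constitutive cytochromes P450, bile acids, hepatocyte identity, glucose metabolism, urea cycle and amino acid breakdown, ER chaperones, ATF4 and amino acid response, NRF2 and oxidative stress, metallothioneins and heat shock, p53 and apoptosis, cell cycle, acute phase, lysosome and autophagy, oxidative phosphorylation, and markers of Kupffer cells and leukocytes, stellate cells, sinusoidal endothelium and cholangiocytes. The cholesterol and lipid lists were chosen knowing that the study reported on them, so their counts are not independent evidence. Of 525 listed genes, 465 had a named probe set and 60 had none. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 24 lists of a comparison. A list of 42 interferon-response genes was added after the data were seen.

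Named genes were the 5 largest rises and 5 largest falls of each drug and of the mean, among genes past the threshold that moved the same way in every pair. Up to 4 members of each called list and 19 genes fixed in advance were added, of which 15 had a probe set of their own. For a difference between drugs, up to 3 genes were named in each direction. A member named because 5 or fewer of its list moved in a direction was chosen after its values were seen.

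Alternatives left out the pair terms, joined the 12 DMSO arrays into 1 control group, used only the arrays of the drugs compared, required a mean log2 value of at least 5 (13367 probe sets), repeated the quantile normalization, centred arrays on their medians, used a trended robust prior, weighted the arrays, required a 2-fold change, averaged the probe sets of a gene, or left out each pair in turn. Those added after the data were seen used preparation as a block, left out preparation 3, or took 1 value per preparation. The model was tested on simulated data. For BZP it called 56 percent of 100 probe sets changed by 0.5 and 100 percent of those changed by 1 on the log2 scale. It called 14 unchanged probe sets for BZP, 1 for TFMPP, 4 for the mean and 10 for the difference of BZP and TFMPP, each of 31042 probe sets in the step. These data held changed probe sets beside the unchanged ones, so the numbers do not give the calls expected where nothing changed. A simulated list of 17 genes shifted by 0.4 was called for each drug and for the mean, and of 23 lists left unshifted, 1 was called for the mean and 0 for each drug. The simulated noise was independent between genes, so these counts do not show the error of the list test where genes are correlated.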

Results

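Gene expression was measured in sandwich-cultured primary rat hepatocytes after 24 h with 4 piperazine designer drugs, to learn which genes respond to concentrations of comparable toxicity. BZP (benzylpiperazine) and MDBP (methylenedioxybenzylpiperazine) carry a benzyl group on the piperazine ring, and TFMPP (trifluoromethylphenylpiperazine) and MeOPP (methoxyphenylpiperazine) a phenyl group. Each drug had 3 treated samples and 3 controls with 0.1 percent DMSO, joined into 12 pairs. The drugs were used at 625, 35, 522 and 467 µM for BZP, TFMPP, MeOPP and MDBP, so their doses differed. Arrays were alike in level, with medians from 4.448 to 4.519 on the log2 scale. Of 57 control probe sets, limma called 0 with each drug and in the mean. At an unadjusted p under 0.05 there were 0 with BZP, 3 with TFMPP, 1 with MeOPP, 0 with MDBP and 4 in the mean. The Dap, Lys, Phe and Thr control transcripts lay at 0.41 to 0.66 with BZP, 0.10 to 0.33 with TFMPP, -0.49 to -0.23 with MeOPP and -0.20 to 0.089 with MDBP.

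Averaged over the 4 drugs, genes of cholesterol synthesis rose while genes of bile acid handling, amino acid breakdown and glucose metabolism fell. The list of cholesterol synthesis lost its call with an estimated correlation (adjusted p = 0.0853 with an estimated correlation), and the other 3 kept theirs. Gpnmb, a lysosome-associated glycoprotein, rose most, by 2.30 ± 0.09 on the log2 scale (SE, n = 12 pairs; 4.94-fold; adjusted p = 4.87e-10). Fads1, a fatty acid desaturase, rose by 2.22 ± 0.12 and Rragd, a Rag GTPase of lysosomal nutrient signalling, by 1.78 ± 0.12. The deepest fall was that of Slc10a1, the sodium-dependent bile acid uptake carrier, at -2.55 ± 0.12 (5.85-fold lower; adjusted p = 1.15e-09). Sult2a6, a bile acid sulfotransferase, changed by -2.34 ± 0.17, Cyp8b1, the sterol hydroxylase that sets the cholic acid share, by -2.27 ± 0.18, Bhmt, which methylates homocysteine, by -2.19 ± 0.14, and Uroc1, an enzyme of histidine breakdown, by -2.10 ± 0.11. All of these moved the same way in 12 of 12 pairs. Albumin (Alb) stood at -0.01 ± 0.04 (adjusted p = 0.874). In limma with Benjamini-Hochberg adjustment, 6952 of 31042 probe sets changed, 3893 higher and 3059 lower, for 4248 genes. Of these probe sets, 202 changed at least 2-fold, 39 higher and 163 lower. Without the pair terms the count was 1927, and with 1 value per preparation it was 4346. The 10 largest changes were all called without the pair terms, as were 59 of 84 named genes. The 12 pairs fell into 5 inferred preparations, while the SE and p-values of the mean take the pairs as independent. With 1 value per preparation the limma adjusted p was 6.17e-05 for Gpnmb and 6.18e-05 for Slc10a1.

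All 17 measured enzymes of cholesterol synthesis rose in the mean of the drugs, from the first steps to the last. Msmo1, a sterol oxidase, rose by 1.60 ± 0.06 (3.02-fold; adjusted p = 5.21e-10), Acat2, at the entry of the pathway, by 1.56 ± 0.10, Idi1, the isoprenoid isomerase, by 1.54 ± 0.06, Sqle, the squalene epoxidase, by 1.32 ± 0.06, and Fdps, which makes farnesyl diphosphate, by 1.11 ± 0.06 (SE, n = 12 pairs). The list median was 0.64, positive in 12 of 12 pairs, with preparations from 0.52 to 1.19 (camera adjusted p = 9.24e-16, or adjusted p = 0.0853 with an estimated correlation). Adjusted over the list alone, 17 also rose. By drug, 13 rose with BZP, 11 with TFMPP, 11 with MeOPP and 12 with MDBP, and adjusted over the list alone 16, 17, 16 and 15. With an estimated correlation the adjusted p was 0.102 for BZP, 0.0275 for TFMPP, 0.0795 for MeOPP and 0.102 for MDBP. The list was chosen knowing the study, so its count is not independent evidence.

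**Figure D1:**
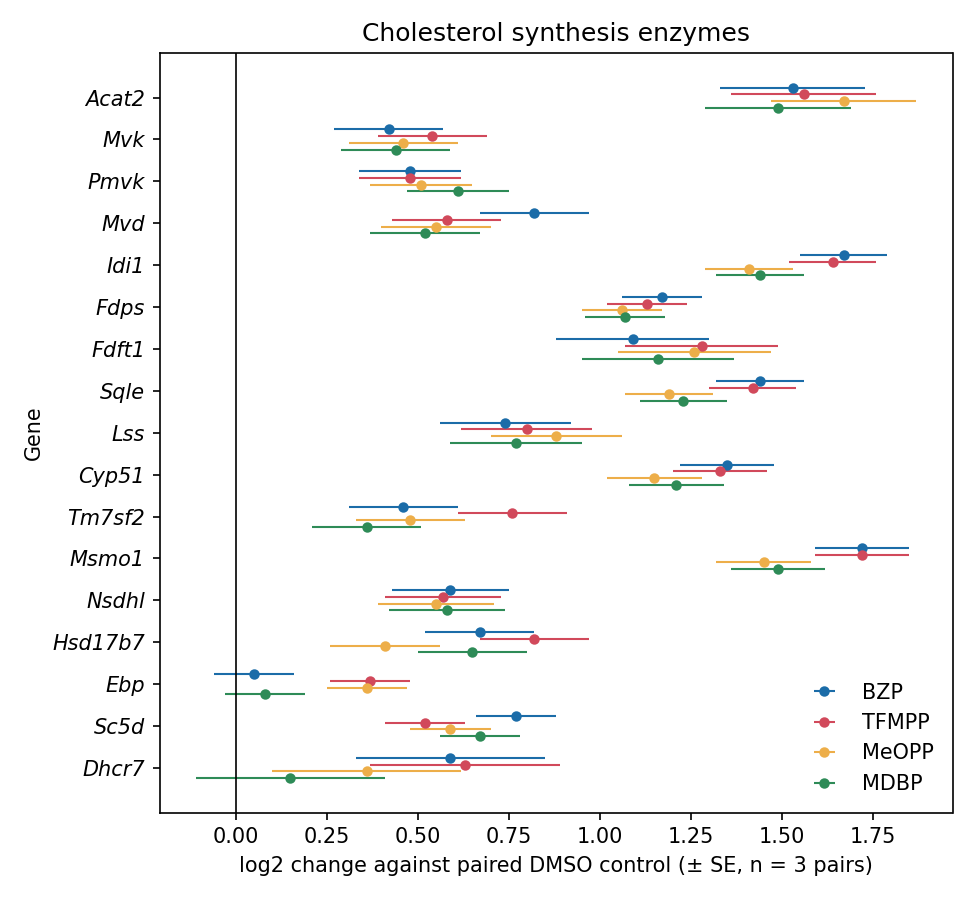
Change of the 17 measured cholesterol synthesis enzymes with each drug, as log2 treated minus paired control on the x axis; points are model estimates and bars the SE of 3 pairs. Every point lies above 0, from 0.05 for Ebp with BZP to 1.72 for Msmo1 with BZP and TFMPP.

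Genes of fatty acid and triglyceride synthesis also rose as a list, with 14 of 24 members higher and 4 lower (adjusted p = 0.00112, or adjusted p = 0.145 with an estimated correlation). The call was also lost among genes with a mean log2 value of at least 5 (adjusted p = 0.073). Fasn, the fatty acid synthase, rose by 1.18 ± 0.12 (2.26-fold; adjusted p = 2.6e-06), Acsl3, an acyl-CoA synthetase, by 0.97 ± 0.08, and Srebf1, the lipogenic transcription factor, by 0.80 ± 0.06 (SE, n = 12 pairs). Scd, the stearoyl-CoA desaturase, rose by 0.67 ± 0.09 (adjusted p = 4.08e-05, and 0.567 without the pair terms). The lower members were Elovl2 (-0.80 ± 0.06), Acaca, Agpat2 and Dgat1. The list median was 0.20 in the mean of the drugs, above 0 in 12 of 12 pairs, with preparations from 0.14 to 0.37. Adjusted over the list alone, 15 rose and 5 fell, and this list too is not independent evidence.

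Sterol regulation and uptake genes moved both ways. Insig1, which retains the SREBP complex in the ER, rose by 1.00 ± 0.07 (SE, n = 12 pairs; adjusted p = 3.26e-08), with Stard4, Npc2, Abca1 and Srebf2. Srebf2, the main activator of cholesterol genes, rose by 0.35 ± 0.07 (adjusted p = 0.00215, 0.098 without the pair terms and 0.0564 with 1 value per preparation). Lcat, Abcg5, Abcg8, Nr1h3 and Insig2 fell, led by Lcat, the plasma cholesterol acyltransferase, at -0.99 ± 0.07. In all 5 of 13 rose and 5 fell, or 6 and 6 adjusted over the list alone, and the list did not pass (median 0.15, adjusted p = 0.693).

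Oxidation of fatty acids and PPAR alpha targets fell in 18 of 24 members. Cyp4a3, a fatty acid hydroxylase, changed by -1.68 ± 0.09 (3.21-fold lower; adjusted p = 1.84e-09), Vnn1, a pantetheinase, by -1.29 ± 0.08, Acaa2, a mitochondrial thiolase, by -1.03 ± 0.06, and Decr1, a dienoyl-CoA reductase, by -0.89 ± 0.06 (SE, n = 12 pairs). Cpt1a, the carnitine palmitoyltransferase that admits fatty acids to mitochondria, changed by -0.63 ± 0.07 in 11 of 12 pairs. Plin2, a lipid droplet protein, was the sole member that rose, by 0.20 ± 0.07 (adjusted p = 0.0462). The median was -0.65, with preparations from -0.92 to -0.55 (adjusted p = 4.38e-16, or adjusted p = 0.0143 with an estimated correlation), and adjusted over the list alone 19 fell and 1 rose. Non-parenchymal markers with a mean log2 value of at least 5 had a median of -0.11 in the same comparison.

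Bile acid genes fell in 17 of 21 members. Besides Slc10a1 and Cyp8b1, Abcb11, the canalicular bile salt export pump, changed by -1.42 ± 0.06 (2.68-fold lower; adjusted p = 5.21e-10), Acox2, a side-chain oxidase, by -1.70 ± 0.09, and Slco1a4, an organic anion carrier, by -1.40 ± 0.10 (SE, n = 12 pairs). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, changed by -1.38 ± 0.16 (adjusted p = 8.34e-06, and 0.186 without the pair terms). Abcc4 alone rose, by 0.27 ± 0.07. The median was -0.65, with preparations from -1.17 to -0.36 (adjusted p = 6.6e-13, or adjusted p = 0.0278 with an estimated correlation), and adjusted over the list alone 17 fell and 1 rose.

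Constitutive cytochromes P450 fell in 19 of 22 members. Cyp4f4 changed by -1.77 ± 0.12 (3.41-fold lower; adjusted p = 4.07e-08), Cyp2a1, a steroid hydroxylase, by -1.65 ± 0.10, and Cyp2a2 by -1.03 ± 0.05 (SE, n = 12 pairs). The median was -0.71, with preparations from -1.04 to -0.38 (adjusted p = 4.38e-16, or adjusted p = 0.0112 with an estimated correlation), and adjusted over the list alone 20 fell and 1 rose. Targets of the xenobiotic receptors CAR and PXR fell in 11 of 16 members. Cyp2b1 and Cyp2b2 were on the list but had no probe set of their own. Aldh1a1 changed by -1.42 ± 0.07 and Cyp3a23-3a1 fell by 1.00 ± 0.12, while Abcc2, a canalicular export pump, rose by 0.60 ± 0.06. Cyp3a18 changed by -1.24 ± 0.11 (adjusted p = 3.67e-07, and 0.122 without the pair terms). The median was -0.34, with preparations from -0.70 to -0.17 (adjusted p = 3.99e-07, or adjusted p = 0.0143 with an estimated correlation), with 13 lower and 1 higher adjusted over the list alone. Among 7 AHR targets, Cyp1a1 rose by 1.17 ± 0.20 in 11 of 12 pairs, and Nqo1 and Tiparp rose too (3 adjusted over the list alone), but the list did not pass (median 0.09, adjusted p = 0.0812). It passed without pair 3 of BZP, at 0.0385, and without preparation 3, at 0.033. By drug it passed with TFMPP (adjusted p = 0.0419, or adjusted p = 0.252 with an estimated correlation) and MDBP (adjusted p = 0.0403, or adjusted p = 0.228 with an estimated correlation). Both calls were lost without the pair terms, at 0.121 and 0.0745, and without 1 pair, at 0.22 without pair 1 and 0.064 without pair 2 of TFMPP, and at 0.0672, 0.0506 and 0.0546 without pairs 1, 2 and 3 of MDBP. With MeOPP the list did not pass (adjusted p = 0.131), but it passed without pair 3 of MeOPP, at 0.0327. Among genes with a mean log2 value of at least 5, MeOPP passed, at 0.0476, and MDBP did not, at 0.0818.

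Breakdown of amino acids and the urea cycle fell in 22 of 23 members. Agxt, which handles glyoxylate, changed by -1.05 ± 0.07 (2.07-fold lower; adjusted p = 4.57e-08), Haao, of the tryptophan pathway, by -0.99 ± 0.07, Gls2, the liver glutaminase, by -0.88 ± 0.06, and Hgd, of tyrosine breakdown, by -0.78 ± 0.06 (SE, n = 12 pairs). The median was -0.60, with preparations from -0.66 to -0.48 (adjusted p = 1.6e-17, or adjusted p = 0.0112 with an estimated correlation), with 22 lower adjusted over the list alone. Glucose metabolism fell in 11 of 19 members and rose in 0 by limma. Gys2, the liver glycogen synthase, changed by -1.80 ± 0.12, Fbp1, a gluconeogenic phosphatase, by -1.72 ± 0.08, Slc37a4, the glucose 6-phosphate carrier, by -1.45 ± 0.06, and Pc, the pyruvate carboxylase, by -1.03 ± 0.09. The median was -0.39, with preparations from -0.50 to -0.31 (adjusted p = 1.72e-08, or adjusted p = 0.0112 with an estimated correlation), with 12 lower and 2 higher adjusted over the list alone. Hepatocyte identity and secreted proteins fell in 15 of 22 members, among them Apob, the core protein of secreted lipoproteins (-1.02 ± 0.06), while Ahsg, Onecut1 and Foxa2 rose. Their median was -0.23, with preparations from -0.31 to -0.13 (adjusted p = 7.25e-08, or adjusted p = 0.0599 with an estimated correlation), with 17 lower and 3 higher adjusted over the list alone. The 3' to 5' difference of control probe sets, a sign of RNA quality, was higher in the treated array in 7 of 12 pairs (exact sign-flip p = 0.698).

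**Figure D2:**
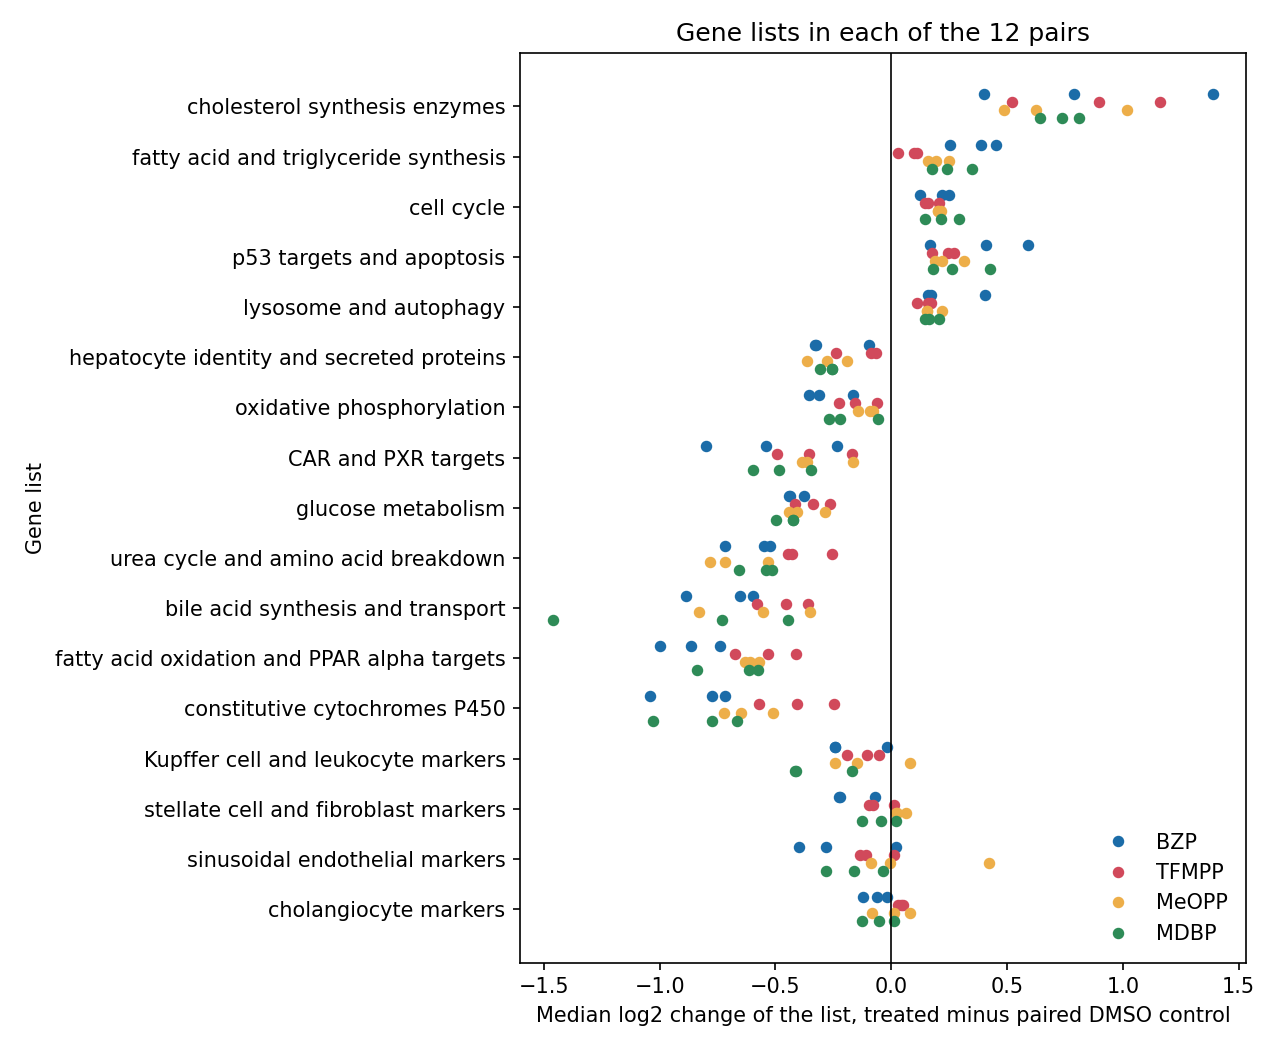
Median log2 change of 17 gene lists, treated minus paired control on the x axis, with a point for each of the 12 pairs coloured by drug. Cholesterol synthesis lies above 0 in 12 pairs, from 0.40 to 1.39, and constitutive cytochromes P450 lie below 0 in 12 pairs, from -1.04 to -0.25; points of the 4 marker lists at the foot lie on both sides of 0.

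Cell cycle genes rose in 12 of 25 members. Mcm6 and Mcm4, subunits of the replicative helicase, rose by 0.85 ± 0.06 (1.8-fold; adjusted p = 3.29e-08) and 0.71 ± 0.07, and the mitotic kinase Bub1 by 0.48 ± 0.07 (SE, n = 12 pairs). The median was 0.14, with preparations from 0.15 to 0.25 (adjusted p = 5.06e-05, or adjusted p = 0.0112 with an estimated correlation), with 14 higher adjusted over the list alone. Targets of p53 rose in 11 of 16 members, among them Mdm2, the ubiquitin ligase of p53, by 0.66 ± 0.06 and Bbc3, a pro-apoptotic factor, by 0.50 ± 0.07, and Sesn1 fell. Cdkn1a, a cell cycle inhibitor, rose by 0.21 ± 0.05 (adjusted p = 0.00506, 0.43 without the pair terms and 0.0543 with 1 value per preparation). The p53 median was 0.26, with preparations from 0.19 to 0.51 (adjusted p = 0.000415, or adjusted p = 0.156 with an estimated correlation), with 11 higher and 1 lower adjusted over the list alone. Lysosome and autophagy genes rose in 14 of 26 members, with Tpp1, a lysosomal peptidase, higher by 0.49 ± 0.06 besides Gpnmb, and Ctss fell. Their median was 0.19, with preparations from 0.14 to 0.26 (adjusted p = 0.000106, or adjusted p = 0.145 with an estimated correlation), with 15 higher and 4 lower adjusted over the list alone.

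ER chaperones fell in 15 of 21 members. Pdia4, a disulfide isomerase, changed by -0.58 ± 0.08 (1.5-fold lower; adjusted p = 8.09e-05; SE, n = 12 pairs), and Eif2ak3, a kinase of the unfolded protein response, alone rose. Hspa5, the main ER chaperone, changed by -0.32 ± 0.08 (adjusted p = 0.0104, 0.186 without the pair terms and 0.196 with 1 value per preparation). The median was -0.26, below 0 in 10 of 12 pairs, with preparations from -0.44 to 0.08 (adjusted p = 1.27e-07, or adjusted p = 0.229 with an estimated correlation), with 19 lower and 1 higher adjusted over the list alone. ATF4 and amino acid response genes rose in 14 of 26 members and Cebpb fell. Mthfd2, a mitochondrial folate enzyme, rose by 0.80 ± 0.13 and Asns, the asparagine synthetase, by 0.74 ± 0.12, each in 11 of 12 pairs, while Ddit3 stood at 0.10 ± 0.11 (adjusted p = 0.614). Their median was 0.30, with preparations from 0.06 to 0.84 (adjusted p = 0.000698, or adjusted p = 0.402 with an estimated correlation), with 17 higher and 2 lower adjusted over the list alone. NRF2 targets rose in 10 of 24 members and Akr7a3, Cat and Sod1 fell (11 and 3 adjusted over the list alone). Hmox1 stood at 0.06 ± 0.08, and the list did not pass (median 0.12, adjusted p = 0.0518), but passed without pair 3 of MeOPP, at 0.0219, without pair 1 of BZP, at 0.0345, without pair 3 of BZP, at 0.0368, without pair 2 of MDBP, at 0.0379, without pair 2 of TFMPP, at 0.0419, and without pair 1 of MDBP, at 0.044. It also passed with repeated quantile normalization, at 0.041, and with the probe sets of a gene averaged, at 0.0329. By drug it passed with BZP (adjusted p = 0.00673, or adjusted p = 0.255 with an estimated correlation) and with TFMPP (adjusted p = 0.0442, or adjusted p = 0.338 with an estimated correlation). Both calls were lost without the pair terms, at 0.0537 and 0.121, and without 1 pair, at 0.0675 without pair 2 of BZP and 0.23 without pair 1 of TFMPP. Of 13 metallothioneins and heat shock genes, Hspb8 and Hsf1 rose and Hspa1a, Mt2A and Hspb1 fell (2 and 4 adjusted over the list alone). That list did not pass (median -0.097, adjusted p = 0.0704), but passed without pair 2 of MeOPP, at 0.0385, without pair 2 of TFMPP, at 0.0419, without pair 2 of BZP, at 0.044, and without pair 3 of MDBP, at 0.0471. It passed with TFMPP (adjusted p = 0.0419, or adjusted p = 0.338 with an estimated correlation) and MeOPP (adjusted p = 0.0303, or adjusted p = 0.364 with an estimated correlation). Both calls were lost without the pair terms, at 0.268 and 0.169, and without pair 3 of the drug, at 0.446 and 0.41.

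Oxidative phosphorylation genes fell by small amounts in 18 of 30 members. Ndufv2, of complex I, changed by -0.38 ± 0.06 (1.3-fold lower; adjusted p = 0.000335; SE, n = 12 pairs). The median was -0.18, with preparations from -0.31 to -0.072 (adjusted p = 1.42e-08, or adjusted p = 0.156 with an estimated correlation), with 21 lower adjusted over the list alone. Acute phase genes fell in 6 of 25 members and Hamp rose, with 6 and 1 adjusted over the list alone. The liver acute phase protein Crp changed by -0.59 ± 0.06 (adjusted p = 4.36e-06, and 0.588 without the pair terms). The median was -0.10, with preparations from -0.24 to -0.0059 (adjusted p = 0.00246, or adjusted p = 0.26 with an estimated correlation).

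Kupffer cell and leukocyte markers fell in 7 of 15 members and Cd68 rose (9 and 2 adjusted over the list alone). Csf1r, a macrophage growth factor receptor, changed by -0.41 ± 0.06 (SE, n = 12 pairs; adjusted p = 0.000185, and 0.337 without the pair terms). The median was -0.21, with preparations from -0.41 to -0.039 (adjusted p = 0.00181, or adjusted p = 0.156 with an estimated correlation), and the call was lost without the pair terms (adjusted p = 0.0644). With MDBP the median was -0.43 (adjusted p = 9.73e-05, or adjusted p = 0.102 with an estimated correlation). Stellate cell markers did not pass as a list (median -0.093, adjusted p = 0.0812), with Col3a1, Col5a2 and Sparc lower and Dcn higher (4 and 1 adjusted over the list alone). They passed lower with BZP (adjusted p = 0.00801, or adjusted p = 0.102 with an estimated correlation), not without pair 3, at 0.0636. Sinusoidal endothelial markers did not pass either (median -0.042, adjusted p = 0.152), with Eng lower both ways, and passed without pair 1 of MeOPP (0.0448). They passed lower with TFMPP (adjusted p = 0.0485, or adjusted p = 0.338 with an estimated correlation), not without the pair terms, at 0.2, without pair 2, at 0.063, or without pair 3, at 0.474. With the other drugs they did not pass in the main fit. With 1 DMSO group they passed lower with BZP (mean -0.45, adjusted p = 0.00788) and MDBP (mean -0.60, adjusted p = 0.00048). BZP also passed under further settings, among them preparation as a block, at 0.0218. MeOPP passed higher without its pair 2 (mean 0.30, adjusted p = 0.0241). Of 8 cholangiocyte markers, 0 changed by limma, also adjusted over the list alone (median -0.024, adjusted p = 0.588).

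With BZP, Gpnmb rose by 2.68 ± 0.17 (SE, n = 3 pairs; 6.4-fold; adjusted p = 8.87e-07), Fads1 by 2.49 ± 0.25, Rragd by 2.27 ± 0.24, Sdcbp2, a syntenin scaffold protein, by 2.23 ± 0.18 and Ampd3, an AMP deaminase, by 2.02 ± 0.28. Slc10a1 changed by -2.86 ± 0.24 (7.25-fold lower; adjusted p = 3.68e-06), Sult2a6 by -2.81 ± 0.35, Cyp8b1 by -2.55 ± 0.36, Bhmt by -2.53 ± 0.28 and Ttc36 by -2.47 ± 0.20. All 10 were called without any 1 of the pairs, but only 2 without the pair terms. In all 2867 probe sets changed, 1476 higher and 1391 lower, for 1795 genes, and 375 of them at least 2-fold. The count was 38 without the pair terms and 1461 without pair 3. ATF4 response genes rose in 11 of 26 members and fell in 0 by limma (median 0.46, adjusted p = 2.41e-05, or adjusted p = 0.336 with an estimated correlation; 15 and 1 adjusted over the list alone). The mean change of the list was 0.48, but 0.73 without pair 1 and 0.25 without pair 3 (adjusted p = 0.0201).

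With TFMPP, Msmo1, Idi1 and Acat2, of cholesterol synthesis, were among the 5 largest rises. Fads1 rose by 1.98 ± 0.25 (SE, n = 3 pairs; 3.95-fold; adjusted p = 0.000708), Msmo1 by 1.72 ± 0.13, Idi1 by 1.64 ± 0.12, Gpnmb by 1.59 ± 0.17 and Acat2 by 1.56 ± 0.20. Sult2a6 changed by -2.09 ± 0.35 (4.25-fold lower; adjusted p = 0.00492), Cyp8b1 by -2.01 ± 0.36, Bhmt by -1.91 ± 0.28, Uroc1 by -1.72 ± 0.22 and Slc10a1 by -1.64 ± 0.24. Of these 10, 8 were called without any 1 of the pairs, Sult2a6 and Cyp8b1 not, and 1, Gpnmb, without the pair terms. In all 551 probe sets changed, 173 higher and 378 lower, for 367 genes, and 75 at least 2-fold. The count was 1 without the pair terms, and 139, 199 and 166 without pairs 1, 2 and 3.

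With MeOPP, Gpnmb rose by 2.31 ± 0.17 (SE, n = 3 pairs; 4.95-fold; adjusted p = 5.27e-06), Fads1 by 2.21 ± 0.25, Csrp3, a muscle LIM protein, by 1.90 ± 0.29, Acat2 by 1.67 ± 0.20 and Msmo1 by 1.45 ± 0.13. Slc10a1 changed by -2.71 ± 0.24 (6.55-fold lower; adjusted p = 8.93e-06), Bhmt2 by -2.20 ± 0.18, Cyp8b1 by -2.17 ± 0.36, Fbxl17l1 by -2.13 ± 0.20 and Aass, of lysine breakdown, by -2.12 ± 0.19. All 10 were called without any 1 of the pairs, but only Gpnmb without the pair terms. ER chaperones fell in 9 of 21 members (median -0.39, adjusted p = 1.86e-10, or adjusted p = 0.177 with an estimated correlation; 15 adjusted over the list alone). In all 1865 probe sets changed, 692 higher and 1173 lower, for 1134 genes, and 210 at least 2-fold. The count was 12 without the pair terms, and 819, 834 and 1226 without pairs 1, 2 and 3.

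With MDBP, Gpnmb rose by 2.64 ± 0.17 (SE, n = 3 pairs; 6.23-fold; adjusted p = 2.19e-06), Rragd by 2.25 ± 0.24, Fads1 by 2.21 ± 0.25, Uap1l1 by 1.67 ± 0.17 and Ndrg1 by 1.57 ± 0.26. Slc10a1 changed by -2.98 ± 0.24 (7.91-fold lower; adjusted p = 5.83e-06), Fbxl17l1 by -2.46 ± 0.20, Sult2a6 by -2.45 ± 0.35, Cyp8b1 by -2.37 ± 0.36 and Bhmt by -2.35 ± 0.28. All 10 were called without any 1 of the pairs, and 3, Gpnmb, Rragd and Uap1l1, without the pair terms. ATF4 response genes rose in 10 of 26 members and fell in 0 by limma (median 0.49, adjusted p = 4.34e-07, or adjusted p = 0.254 with an estimated correlation; 15 and 1 adjusted over the list alone). The mean change of that list was 0.54, but 0.34 without pair 3 (adjusted p = 0.000382). In all 2167 probe sets changed, 1000 higher and 1167 lower, for 1383 genes, and 255 at least 2-fold. The count was 28 without the pair terms, 959 without pair 2 and 821 without pair 3.

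**Figure D3:**
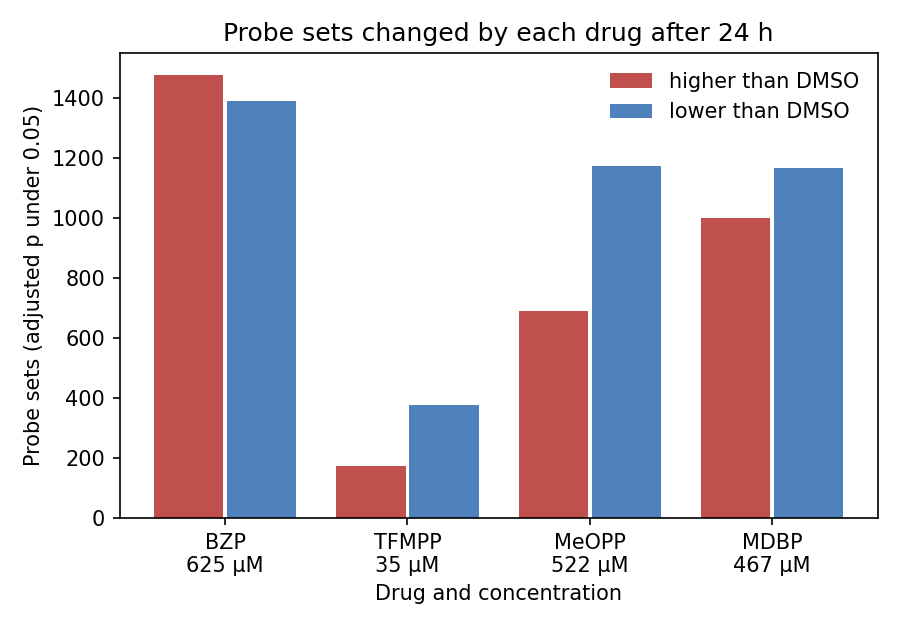
Number of probe sets past an adjusted p of 0.05 with each drug, higher and lower than the paired DMSO control, with the concentration in µM under each name. TFMPP has 173 higher and 378 lower, and BZP 1476 higher and 1391 lower; the counts carry no error bar and depend on the pair terms.

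The drugs shared many of their calls. Higher with all 4 drugs were 97 probe sets of 72 genes, and lower 297 of 202 genes, where independent lists of these lengths would give 0.0059 and 0.024. BZP and MDBP shared 649 higher and 849 lower probe sets (47.5 and 52.3 for independent lists), and TFMPP and MeOPP 121 and 339 (3.86 and 14.3). The tests of the 4 drugs used 1 shared estimate of the spread of each probe set. Probe sets with a small spread are therefore called more easily with every drug, and the numbers for independent lists are too low as a baseline. Opposite calls numbered 2 for BZP with TFMPP, 2 for BZP with MeOPP, 1 for MeOPP with MDBP and 0 in the other 3 comparisons. Across probe sets, which are not independent replicates, changes with BZP and MDBP correlated at r = 0.80 and those with TFMPP and MDBP at r = 0.625. Each drug had its own controls, but pairs of different drugs came from the same inferred preparations. Over probe sets called in the other 3 drugs, the slope of a drug's changes on their mean was 1.17 ± 0.17 for BZP, 0.596 ± 0.06 for TFMPP, 0.915 ± 0.2 for MeOPP and 1.05 ± 0.19 for MDBP (SD, n = 3 pairs).

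BZP and TFMPP, which differ in a benzyl against a trifluoromethylphenyl group and in dose (625 against 35 µM), differed at 16 probe sets of 13 genes, 4 higher and 12 lower with BZP. On simulated data the same comparison called 10 unchanged probe sets, beside 100 probe sets changed by 0.5 and 100 by 1 with BZP. That number does not give the calls expected where nothing differs. Usp18, a negative regulator of interferon signalling, changed by -1.38 with BZP and stood at 0.68 with TFMPP, a difference of -2.06 ± 0.32 (SE, n = 3 pairs each; adjusted p = 0.0292). Oas1a, an antiviral oligoadenylate synthetase, differed by -1.81 ± 0.27, and Apol9a by -1.66 ± 0.23. Sdcbp2 differed by 1.85 ± 0.25 (adjusted p = 0.0124), Dnase2b, a DNase, by 1.40 ± 0.18, and the noncoding RNA Pvt1 by 1.20 ± 0.20. The others, named after their values were seen, were Gpam at 1.00 and, lower, the class I antigen gene RT1-S3 with 4 probe sets, Gstt3, Irf9, Irgm2, Dtx3l and Amigo1. The count was 0 without the pair terms, 0 without pair 1 of BZP, pair 2 of TFMPP or pair 3 of TFMPP, 10 without pair 2 of BZP, 6 without pair 3 of BZP and 34 without pair 1 of TFMPP. The calls of Usp18, Oas1a, Apol9a, Sdcbp2, Dnase2b and Pvt1 were each lost without at least 1 pair.

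Interferon-response genes, a list of 42 added after the data were seen, differed between BZP and TFMPP by a median of -0.69 (adjusted p = 5.06e-28, or adjusted p = 0.0763 with an estimated correlation). With BZP 12 fell and 0 rose by limma (median -0.24, adjusted p = 1.74e-06, or adjusted p = 0.249 with an estimated correlation), and 14 fell and 1 rose adjusted over the list alone. With TFMPP 4 rose and 0 fell (median 0.42, adjusted p = 3.05e-10, or adjusted p = 0.156 with an estimated correlation), and 18 rose adjusted over the list alone. Irf9, a subunit of the interferon-activated transcription factor, stood at -0.70 with BZP and 0.50 with TFMPP. In the mean of the drugs 5 rose and 8 fell, or 6 and 8 adjusted over the list alone, with a median of 0.045 and a mean of 0.022 while the test pointed down (adjusted p = 0.693). Within preparations 1 and 2 the list means differed by -0.32 and -1.26, where the difference of 2 single pairs had an SD of 0.365. The list median was -0.11 in pair 1 of TFMPP, 0.73 in pair 2 and 0.41 in pair 3, so the rise was absent from 1 of 3 pairs.

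For the other 5 differences between drugs, limma called 0 probe sets, with and without the pair terms. The benzyl compounds BZP and MDBP, at 625 and 467 µM, gave 1150 probe sets with an unadjusted p under 0.05, and the phenyl compounds TFMPP and MeOPP, at 35 and 522 µM, gave 1721. The numbers were 2151 for BZP against MeOPP, 2001 for TFMPP against MDBP and 1519 for MeOPP against MDBP. The lowest adjusted p was 1, 0.7, 0.29, 0.227 and 0.963 in the same order. At an unadjusted p under 0.05, a share of 0.05 of the 31042 probe sets would pass without any difference. BZP against MDBP and MeOPP against MDBP lay below that share. The 95 percent interval of a difference reached 0.335 on the log2 scale to either side at the median probe set, against 0.237 for a single drug and 0.119 for the mean, before adjustment over the probe sets. With preparation as a block in place of pairs, TFMPP and MeOPP differed at 302 probe sets, TFMPP and MDBP at 156, BZP and TFMPP at 137 and BZP and MeOPP at 1. That block was clustered from these DMSO arrays, and its fit does not set a treated array against its own control. TFMPP and MeOPP pairs lay in the same preparations, so there the treated arrays were compared directly. These counts are therefore not a stronger test of the same differences. Without 1 pair the count was 1 for BZP against MeOPP (pair 2 of MeOPP) and 1 for TFMPP against MDBP (pair 1 of TFMPP, or pair 1 of MDBP).

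The 26 ATF4 and amino acid response genes had a mean change of 0.51 ± 0.42 in the 6 pairs of the benzyl compounds and 0.053 ± 0.16 in the 6 of the phenyl compounds (SD; two-sided exact permutation p = 0.039 over 924 splits). The permutation took pairs as units, though pairs of the same drug are not independent samples of its kind. This comparison was added after the counts by drug were seen. The phenyl compounds passed under other settings: MeOPP at a mean of 0.39 with 1 DMSO group (adjusted p = 0.000493) and 0.23 with preparation as a block (adjusted p = 0.0271), and TFMPP at 0.20 with 1 DMSO group (adjusted p = 0.0154). Within preparation 1 the difference was -0.11 and within preparation 2 it was 0.48. No other preparation held both kinds of compound. Over single probe sets, limma called 0 between the kinds, with 2421 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0545.

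**Figure D4:**
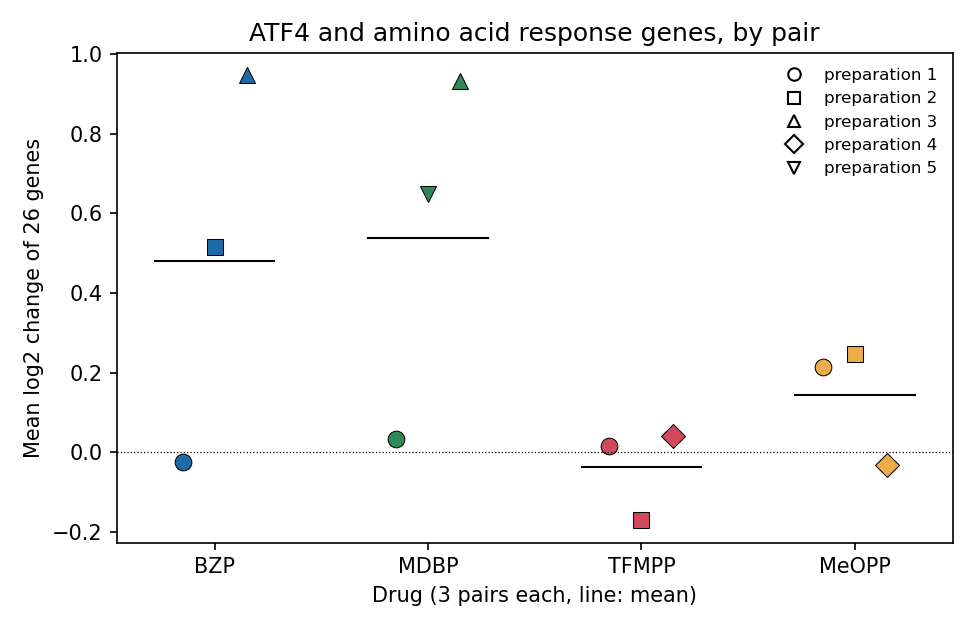
Mean log2 change of the 26 ATF4 and amino acid response genes in each pair, with a symbol for the inferred preparation, on the y axis, by drug on the x axis; lines are means of 3 pairs. The highest values, 0.947 with BZP and 0.933 with MDBP, come from preparation 3.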

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

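The test of the difference between BZP and TFMPP was planned; the interferon list and the 3 tests of explanations below were chosen, or given their final criterion, only after the result was seen.

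A test of the difference itself singled out 16 probe sets whose change with BZP was unlike that with TFMPP. The named ones were Sdcbp2 at 1.85, Dnase2b at 1.40 and Pvt1 at 1.20 on the log2 scale, higher with BZP, and Apol9a at -1.66, Oas1a at -1.81 and Usp18 at -2.06, lower with BZP. On simulated data the same comparison called 10 unchanged probe sets, beside 100 probe sets changed by 0.5 and 100 by 1 with BZP. That number does not give the calls expected where nothing differs. Of the 10 splits of the 6 pairs, only 1, the real split itself, gave 16, the highest other gave 0, and 10 splits are too few for a share under 0.05. The doses of the compounds differed, and the count was 0 under several of the left-out pairs.

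The 42 interferon-response genes had a median of -0.691 for BZP minus TFMPP, and 5 of the 13 genes above belong to that list. The test for fewer leukocytes in the BZP cultures asked whether leukocyte markers fell as much as the list. The 9 markers fell less, with a median difference of -0.0924 and a lowest of -0.405 (SE 0.076 across markers, not cultures). Interferon genes need not fall in step with leukocyte markers, so a smaller loss of leukocytes is not ruled out. Sequence differences of the MHC between animals stay open for the RT1-S3 probe sets: the test counted 12 called probe sets of other genes, but these were already known and the interferon list holds no RT1 gene, so it decides nothing. The tests made did not tell an origin of the pairs in different preparations apart from a difference between the drugs. BZP was lower in 2 of 2 preparations that held both (-0.316 and -1.26), as first required to rule the preparations out, but each value rests on 1 pair of each drug. In each preparation that held BZP, its list mean was the lowest of any pair (-0.429, -0.426 and -0.257). No preparation held a drug more than once, so the spread between pairs of a drug within a preparation was not seen directly. A joint fit of drugs and preparations to the pair means of the list was not made. Across preparations the difference of 2 single pairs had an SD of 0.365, a spread that includes the preparations, and the smaller difference, -0.316, lies within it. The demand that both exceed that SD was added after they were known.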

How the results depend on the processing

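Preparation as a block, the loss of preparation 3 and 1 value per preparation were chosen only after the data were seen; the other alternatives were planned. Without the pair terms (no replicate block) BZP had 38, TFMPP 1, MeOPP 12, MDBP 28, the mean 1927 and BZP against TFMPP 0 changed probe sets; with all DMSO arrays as 1 group they had 386, 20, 796, 294, 2156 and 0. The pair terms remove the shared level of each pair, which correlated at 0.612 to 0.802. With only the arrays of the drugs compared, BZP had 1063, TFMPP 1092 and the difference of BZP and TFMPP 5. Repeated quantile normalization gave that difference 10. Array weights gave TFMPP 1357, BZP against TFMPP 26 and TFMPP against MDBP 1. A 2-fold minimum, which removes small changes by construction, left 375, 75, 210, 255 and 202 for the drugs in the same order and the mean. Preparation as a block gave 4672, 1762, 3902 and 3946 for the drugs, 302 for TFMPP against MeOPP, 137 for BZP against TFMPP, 1 for BZP against MeOPP and 156 for TFMPP against MDBP. This block was clustered from the same DMSO arrays, and its fit does not set a treated array against its own control. Without preparation 3 BZP had 1528, MDBP 1032 and BZP against TFMPP 6, with fewer pairs, and 1 value per preparation gave the mean 4346. Leaving out 1 pair at a time gave 1461 to 2464 for BZP, 139 to 199 for TFMPP, 819 to 1226 for MeOPP, 821 to 1625 for MDBP, 6002 to 6847 for the mean, 0 to 34 for BZP against TFMPP, 0 to 1 for BZP against MeOPP and TFMPP against MDBP, and 0 for the other differences. The mean change of the cholesterol list was 0.7458 to 1.073 for BZP, 0.8285 to 1.094 for TFMPP, 0.6813 to 0.9806 for MeOPP, 0.7817 to 0.8905 for MDBP and 0.84 to 0.9219 for the mean. An estimated correlation left its size as it was (0.9153 for BZP, 0.8445 for MeOPP, 0.8196 for MDBP, 0.8823 for the mean) and ended those calls; over all lists and comparisons it ended 54 of 89 calls. Median centring, the trended robust prior and the limit on dim probe sets moved no count of probe sets by over 1.5 times. The direction reversed for the Kupffer list with BZP (0.03381 with 1 DMSO group, 0.02143 with preparation as a block) and, with 1 DMSO group and TFMPP, for ATF4 (0.2033), metallothioneins (0.02048) and sinusoidal markers (0.1827). Without the pair terms 14 of 89 list calls and 290 of 360 named gene calls were lost and 0 reversed. Except where stated, the cause of these shifts was not tested. Signal over background was not measured, and 13367 of 31042 probe sets had a mean log2 value of at least 5.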

Other observations

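The choice of genes outside the lists, the ATF4 comparison, the tests of its explanations, and the tests of cell share and RNA quality were made only after the results were seen; the test of the metabolic fall by preparation was written after that fall and the preparations were known but before its own values were seen, and the splits were planned.

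Many of the genes that moved with all 4 drugs and in 12 of 12 pairs lay outside the lists, 52 of 72 higher genes and 165 of 202 lower ones. Among the higher were Rab30, a small GTPase of the Golgi, at 1.34 ± 0.06 in the mean of the drugs (SE, n = 12 pairs; 2.53-fold; limma adjusted p = 5.21e-10), Stx3, a membrane fusion syntaxin, at 1.26 ± 0.08, Cables1 at 1.04 ± 0.08, Il1r2, the decoy receptor of interleukin-1, at 1.01 ± 0.06, Dpysl2 at 1.00 ± 0.05, and Flcn, folliculin, a partner of the Rag GTPases at the lysosome, at 0.81 ± 0.06. Among the lower were Bhmt2 at -1.92 ± 0.09, the medium-chain acyl-CoA synthetases Acsm5 (-1.86 ± 0.08) and Acsm1 (-1.55 ± 0.07), Ftcd, of histidine breakdown, at -1.80 ± 0.10, Urad, of urate breakdown, at -1.78 ± 0.15, Dpyd, which starts pyrimidine breakdown, at -1.57 ± 0.08, and Bbox1, the last enzyme of carnitine synthesis, at -1.55 ± 0.10.

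The 109 metabolic genes of the P450, amino acid, bile acid, fatty acid oxidation and glucose lists had a median of -0.636 in the mean of the drugs. A lower share of hepatocytes among the cells would raise the markers of every other cell type by at least as much, but 27 such markers had a highest pair median of 0.223 and lay below 0 in 11 of 12 pairs. Lower RNA quality in treated samples would spare the 5 pairs whose treated array had no higher 3' to 5' difference, but the highest metabolic median among them was -0.604. No preparation carried the fall alone, since the highest median of any pair was -0.313. An effect of the drugs on the hepatocytes themselves may remain, as a hypothesis found and tested on the same data. The RNA quality test replaced, after its result was seen, a count of pairs with a higher difference (7 of 12, exact sign-flip p = 0.698).

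The ATF4 and amino acid response genes were higher with BZP and MDBP than with TFMPP and MeOPP by 0.456. The smallest difference left after any 1 pair was removed was 0.368. That test asked only for a value above 0, which no pair mean was extreme enough to undo, so it decides little. The permutation was not repeated without a pair. The type of piperazine may account for the difference (exact permutation p = 0.039), though that permutation test ignores preparations, and doses differed. It also took pairs of the same drug as independent samples of a type. With drugs as units there are too few of each type for such a test. The tests made did not tell the preparations apart from the type, because the benzyl pairs were higher in only 1 of the 2 preparations that held both (-0.111 and 0.477), and the highest pairs, 0.947 and 0.933, share preparation 3. No preparation held a drug more than once, so the spread between pairs of a drug within a preparation was not seen directly. A joint fit of drugs and preparations to the pair means of the list was not made. A demand that each difference exceed its SD across preparations (0.348 and 0.426) was added after both differences were known.

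Paired differences of different drugs correlated at a mean of 0.499 within a preparation and 0.422 between preparations (one-sided exact permutation p = 0.0108 over 1296 orders). The preparations were clustered from the same DMSO arrays that enter these differences, and the permutation did not repeat the clustering. Alike controls alone can raise the value within a preparation, so the test does not show that the response to the drugs depends on the preparation.

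For each drug, only 1 of the 10 splits of its 6 arrays, the real split itself, reached the real count of changed probe sets, and 10 splits are too few for a share under 0.05. The real and highest other counts were 2867 and 248 for BZP, 551 and 0 for TFMPP, 1865 and 17 for MeOPP and 2167 and 0 for MDBP. Of the 4 splits of each that part every pair, all but the real one gave 0. For the mean of the drugs, only 1 of 100 splits that part all 12 pairs, the real split itself, reached the real 6952, a share under 0.05. The highest other, 5209, exchanged only pair 2 of TFMPP and so nearly repeats the real split. For the differences with a real count of 0, 10 of 10 splits gave as many, which no split could fail to do. The highest other was 3 for BZP against MDBP and for MeOPP against MDBP, 1 for TFMPP against MDBP, and 0 for the rest. These splits too are too few for a share under 0.05.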
